A study of Mus musculus with 8 samples.

How the data were processed

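The data are RNA sequencing libraries of mouse Lewis lung carcinoma tumors and of cells sorted from them. Per the labels, 200 ng of RNA per library was turned into cDNA with oligo-dT priming, and libraries were read at 50 bp on an Illumina HiSeq1500. The deposited table holds RPKM values (reads per kilobase of transcript per 1e6 reads) that the authors computed, with 1 column per library. Their processing notes name STAR, HOMER and the mouse genome build mm9, without versions. Which reads made up the total behind the RPKM, the filters and the strand setting are not given in the sources used here. The values are labelled RPKM and are not counts, and their column sums differ between libraries, so they are not TPM either.

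The table lists 31645 RefSeq transcripts. The 3 transcripts without a gene name were left out, and they held at most 0.0032% of the summed RPKM of a library. For each of the 4341 symbols with more than 1 transcript, the transcript with the highest mean over the 8 libraries was kept, which left 23952 symbols. Genes with an RPKM of at least 1 in at least 2 libraries were tested (13311 genes), on log2(RPKM + 1) and with no rescaling of the deposited values. Genome coordinates are not printed, because the annotation at hand belongs to a later build than mm9. That annotation was used for transcript lengths alone, matched by RefSeq accession for 97.4% of transcripts.

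Read counts are not part of the table. Depth was estimated from the lowest RPKM values, from 0.04 up to the level of 6 reads, as the depth at which most of these values fall within 0.05 of a whole number of reads. The estimates lay between 4.28 and 10.37 M reads. RPKM values carry no counting error of their own, so count-based tests were not run, and precision rests on the spread between the 2 libraries of a group.

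The 4 groups (Total tumor, LLC, Fibroblast and TAM) of 2 libraries each were taken from the labels. All 6 pairs of groups were compared with limma's test, with 1 fit over all 8 libraries and a mean-variance trend. The fit had 4 residual degrees of freedom and a prior of 3.62. Benjamini-Hochberg adjusted p-values under 0.05 over the 13311 genes were called. Genes highest in 1 population were those called higher than in both other sorted populations, and genes highest in Total tumor those called higher than in all 3. The sizes of these sets were set beside those of independent lists and of 20 simulations, since the comparisons share libraries.

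There were 37 gene lists of cell types and pathways, fixed before the data were examined together with the comparisons, the tests, the rule for named genes and the alternatives not described as added later. Lists with at least 4 tested members (32 of the 37) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation and with fry, which asks whether the members move 1 way on balance. The members called are counted over all genes tested and, where the count differs, adjusted over the list alone.

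Named genes were chosen by a rule. It takes the 8 largest called changes in each direction per comparison of sorted populations and the 5 largest per comparison with Total tumor. These had to have a mean RPKM of at least 10 in the higher group and no overlap between the libraries. The 5 genes with the largest margin were added for each set of genes highest in 1 group. For a list that is described, up to 2 called members in each direction are named. Mrc1, Mrc2, Ctsb, Ctsk, Ctsl, Ctss, Lgmn, Mmp2, Mmp9, Mmp13, Mmp14, Col1a1, Col1a2, Col3a1, Ccr2, Arg1 and Emr1 (which encodes F4/80) are named in any case, for the study's subject and its sort gates. Genes named outside the rule are marked as chosen after their values were seen.

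The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at an RPKM of 5, upper-quartile rescaling and quantile normalization. Further ones were no variance trend, a fit of only the groups compared, a term for the replicate number, a 2-fold minimum change, the mean over transcripts and a fit without each library in turn. A correction of each library for a lowess trend on transcript length was added after Total tumor 2 was seen to depend on length. A fit of protein-coding accessions only was added after microRNAs and small nucleolar RNAs were seen among the largest changes.

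The procedure was tested on simulated data with 13311 genes and the spread of these libraries. Of 50 genes given a log2 difference of 2 between TAM and LLC, 70% were called in the right direction. At a log2 difference of 1 it was 6%, at 3 it was 96%, and 15 of 13111 unchanged genes were called. Between TAM and Fibroblast these shares were 6, 68 and 98%, with 13 unchanged genes called. The differences were put into TAM alone, so Fibroblast and LLC differed in no gene, and between them 1 of 13111 genes was called. Of the 13311 simulated genes, 13111 were unchanged. Between the real TAM and LLC libraries limma called 2048 genes higher and 3659 lower, down to a log2 difference of 0.57. An adjusted p under 0.05 is harder to reach where few genes differ. The shares above therefore do not tell how often real differences of these sizes were called. All 10 shifted lists and none of 20 unchanged lists were called by camera (0 of 20 by the preset and by the estimated correlation). The simulated genes varied independently of each other, while the correlation estimated within the real lists reached 0.815. The simulation therefore does not tell how either version of camera does on correlated lists such as these.

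The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.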

Results

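RNA was sequenced from Lewis lung carcinoma (LLC) tumors, which a mouse lung carcinoma cell line had formed under the skin of mice. The injected tumor cells carried the red fluorescent protein dTomato, and the host mice expressed green fluorescent protein (GFP) with Col1a1, a collagen gene of fibroblasts. Fluorescent collagen was injected 24 h before the cells were sorted. The 8 libraries formed 4 groups of 2. These were whole tumors (Total tumor), dTomato-positive cells (LLC), GFP-positive cells (Fibroblast) and tumor-associated macrophages (TAM), sorted as F4/80-positive, collagen-positive cells without dTomato or GFP. The labels do not say whether the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

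The estimated depth was 9.96 and 4.7 M reads in the Total tumor libraries, 10.37 and 4.28 M in LLC, 10.37 and 4.71 M in Fibroblast, and 8.52 and 4.46 M in TAM. Between 57.8 and 62.3% of the low values used for this estimate lay within 0.05 of a whole number of reads. At a depth fixed beforehand 10% would do so by chance. The depth was chosen to make most values whole, so the chance share here is higher, and it was not computed. At these depths 1 read on a 2 kb transcript gave between 0.048 and 0.117 RPKM. The summed RPKM ran from 462116 in Total tumor 1 to 664084 in Total tumor 2. The 10 most abundant transcripts held between 3.74% of it in Total tumor 1 and 8.7% in TAM 1, and between 10899 genes (TAM 1) and 12238 genes (Total tumor 1) reached 1 RPKM.

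The libraries also differed in scale. The median log2 difference over all 13311 genes tested was -0.38 for TAM minus LLC, 0.13 for TAM minus Fibroblast, -0.46 for Fibroblast minus LLC, -0.36 for TAM minus Total tumor, -0.03 for LLC minus Total tumor and -0.51 for Fibroblast minus Total tumor. Upper-quartile rescaling moved these medians to -0.21, -0.10, -0.05, -0.12, 0.05 and -0.01, and quantile normalization to -0.15, 0.10, -0.19, -0.01, 0.08 and -0.13. Medians of gene lists are given relative to the median of all genes of the same comparison.

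TAM were first set against fibroblasts, to see which of these populations carried transcripts for taking up and digesting collagen and which for making it. The gates set part of the answer in advance. Fibroblast was sorted on GFP expressed with Col1a1, and TAM as GFP-negative cells, so a Col1a1 difference follows in part from the sort. Only TAM were sorted as collagen-positive. Mrc1 (NM_008625), the macrophage mannose receptor, which binds and internalizes collagen, stood at 514 ± 195 RPKM (SD, n = 2) in TAM and 6.30 ± 3.42 in Fibroblast (log2 difference 6.17, SE 0.87, adjusted p = 0.000987). Mrc2 (NM_008626), which encodes the related collagen receptor Endo180, lay the other way, at 1.25 ± 1.18 RPKM in TAM and 84.8 ± 12.0 in Fibroblast (log2 -5.35, SE 0.41, adjusted p = 0.00012). The lysosomal proteases Ctss, Lgmn and Ctsb reached 2736 ± 155, 2021 ± 221 and 2037 ± 280 RPKM in TAM, with log2 differences of 6.19, 3.53 and 2.59 from Fibroblast (adjusted p = 0.000623, 0.000522 and 0.00118). Ctsk (NM_007802), the collagen-degrading cathepsin of osteoclasts, was higher in Fibroblast, at 218 ± 25.5 RPKM against 15.6 ± 0.595 in TAM (log2 -3.72, adjusted p = 0.000188). Arg1, an enzyme of arginine breakdown, stood at 1445 ± 304 RPKM in TAM and 13.9 ± 8.50 in Fibroblast (log2 6.71, adjusted p = 0.000474). The collagen transcripts Col1a1, Col1a2 and Col3a1 reached 4757 ± 788, 4277 ± 387 and 9519 ± 139 RPKM in Fibroblast, and their log2 differences in TAM were -6.61, -6.62 and -6.05 (adjusted p = 0.00056, 0.000799 and 0.00052).

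**Figure D1:**
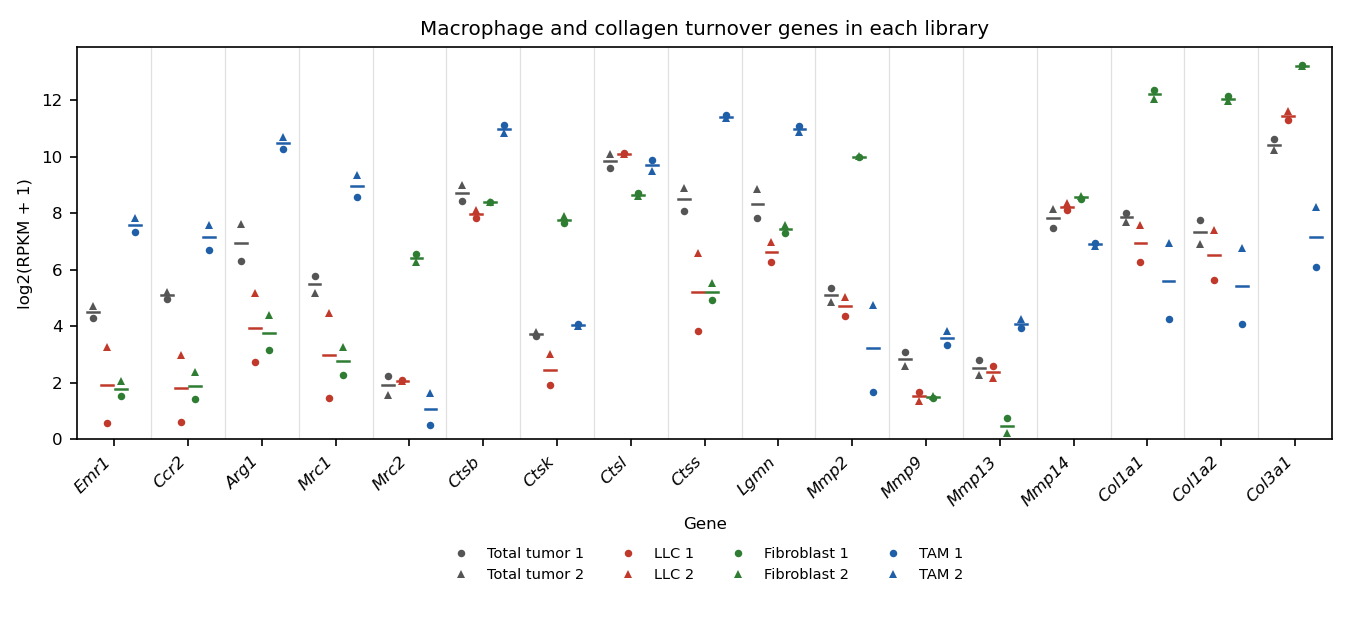
Expression of 17 genes of collagen turnover and of the sort gates in the 4 groups, on a log2(RPKM + 1) scale; each point is 1 library and each bar the mean of 2. Mrc1, Ctss and Lgmn are highest in TAM, while Mrc2, Ctsk, Mmp2, Col1a1 and Col1a2 are highest in Fibroblast, where Col1a1 reaches a mean of 4757 RPKM.

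The collagen uptake receptors split between TAM and Fibroblast. Of 13 tested, 5 were higher in TAM, among them Mrc1 and Stab1 (log2 5.66), and 6 were lower, among them Mrc2 and the collagen-binding integrin subunit Itga11 (log2 -4.84), while 2 did not pass (5 higher and 7 lower adjusted over the list alone). Their median was -0.85 (-0.72 before the median of all genes was taken off, with a mean of 0.24), and camera ranked them lower (adjusted p = 0.536, and adjusted p = 0.829 with an estimated correlation). Among 15 lysosomal cathepsins and legumain, 8 were higher in TAM, with Ctss and Ctsc (log2 5.31) in the lead, and Ctsk and Ctsf (log2 -2.50) were lower (median 1.51, adjusted p = 0.0287, and adjusted p = 0.552 with an estimated correlation). Without Fibroblast replicate 1 the p of that list was 0.066, in a range over its alternatives from 0.0169 to 0.552. Of 29 lysosome structure and hydrolase genes 19 were higher in TAM, such as Cd68 (log2 6.17), and 1 was lower (median 1.28, adjusted p = 3.94e-06, and adjusted p = 0.303 with an estimated correlation). Ctsl, another lysosomal protease, did not pass, at 834 ± 157 RPKM in TAM and 404 ± 15.4 in Fibroblast (log2 1.03, adjusted p = 0.0968). It passed without Total tumor replicate 1 (adjusted p = 0.011) or replicate 2 (0.0121), without the variance trend (0.0206), with only the groups compared (0.0354) and after the length correction (0.017), in a range over its alternatives from 0.011 to 0.382.

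Matrix metalloproteinases, which cleave matrix outside the cell, lay in both directions between TAM and Fibroblast. Of 16, 4 were higher in TAM, including Mmp12 (51.2 ± 15.2 RPKM, log2 4.90), Mmp13 (16.2 ± 2.84 RPKM, log2 3.62) and Mmp9 (log2 2.10), and 7 were lower, including Mmp2 (log2 -6.78) and Mmp3 (log2 -5.33). Their median was -0.25 (adjusted p = 0.47, and adjusted p = 0.606 with an estimated correlation). Mmp2, a gelatinase, stood at 1028 ± 34.3 RPKM in Fibroblast and 14.2 ± 17.0 in TAM. Mmp14, its membrane-bound activator, was lower in TAM at 119 ± 6.17 against 378 ± 19.2 RPKM (log2 -1.66, adjusted p = 0.00525), a call that ended without Fibroblast replicate 2 (adjusted p = 0.0501, range over its alternatives 0.000471 to 0.0501). Of 10 protease inhibitors 8 were lower in TAM, with Serpine2 (log2 -5.41) and Timp3 (log2 -5.31) in the lead, and 2 higher, the cystatins Cstb and Cst3 (median -3.93, adjusted p = 0.000661, and adjusted p = 0.249 with an estimated correlation). The Cstb call (log2 2.52, adjusted p = 0.00543) ended without Fibroblast replicate 1 (0.0523, range 0.000193 to 0.0523). The Cst3 call (log2 2.17, adjusted p = 0.0126) ended without Fibroblast replicate 1 (0.0834), Fibroblast replicate 2 (0.102) or TAM replicate 1 (0.0796), in a range from 0.000359 to 0.102.

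All 8 fibrillar collagens and all 19 other collagens tested were lower in TAM than in Fibroblast, with medians of -5.94 and -3.33 (adjusted p = 1.27e-06 and 1.41e-11, and adjusted p = 0.249 for each with an estimated correlation). So were 16 of 23 collagen modification and crosslinking genes, such as Loxl1 (log2 -6.63) and Loxl2 (log2 -5.95), with a median of -3.93 (adjusted p = 2.57e-09, and adjusted p = 0.249 with an estimated correlation). Of 32 matrix glycoproteins and proteoglycans 27 were lower, such as the proteoglycan Dcn (log2 -6.50), and 3 higher, with Tgfbi (log2 4.57) in the lead, or 28 and 3 adjusted over the list alone (median -5.29, adjusted p = 3.32e-12, and adjusted p = 0.249 with an estimated correlation). Fibroblast identity genes were lower in 18 of 19, for example Clec3b (log2 -6.91, median -5.75, adjusted p = 2.15e-11, and adjusted p = 0.249 with an estimated correlation). Of other cell types, all 10 pericyte genes were lower in TAM (median -3.82, adjusted p = 5.55e-07, and adjusted p = 0.249 with an estimated correlation). Neutrophil genes were higher in 5 of 8 and lower in 1, or 6 and 1 adjusted over the list alone (median 2.46, adjusted p = 0.0163, and adjusted p = 0.499 with an estimated correlation). Beside these groups, fibrillar collagens stood at a median of 0.546% of their Fibroblast level in TAM 1 and 2.83% in TAM 2 (6 genes), and fibroblast identity genes at 0.512% and 2.75% (17 genes). All 22 macrophage identity genes were higher in TAM, such as C1qc (2371 ± 596 RPKM, log2 6.34) and C1qa (log2 6.26), with a median of 5.69 (adjusted p = 2.15e-11, and adjusted p = 0.266 with an estimated correlation).

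Between TAM and Fibroblast, 2314 genes were higher in TAM and 2300 lower by limma (2037 and 2140 with at least a 2-fold difference). Without Fibroblast replicate 1 the higher genes numbered 1424, without Fibroblast replicate 2 they numbered 1382, and without TAM replicate 1 1485. Camera called 11 lists higher and 9 lower of 32, 0 of them with an estimated correlation, and 21 were called by fry.

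**Figure D2:**
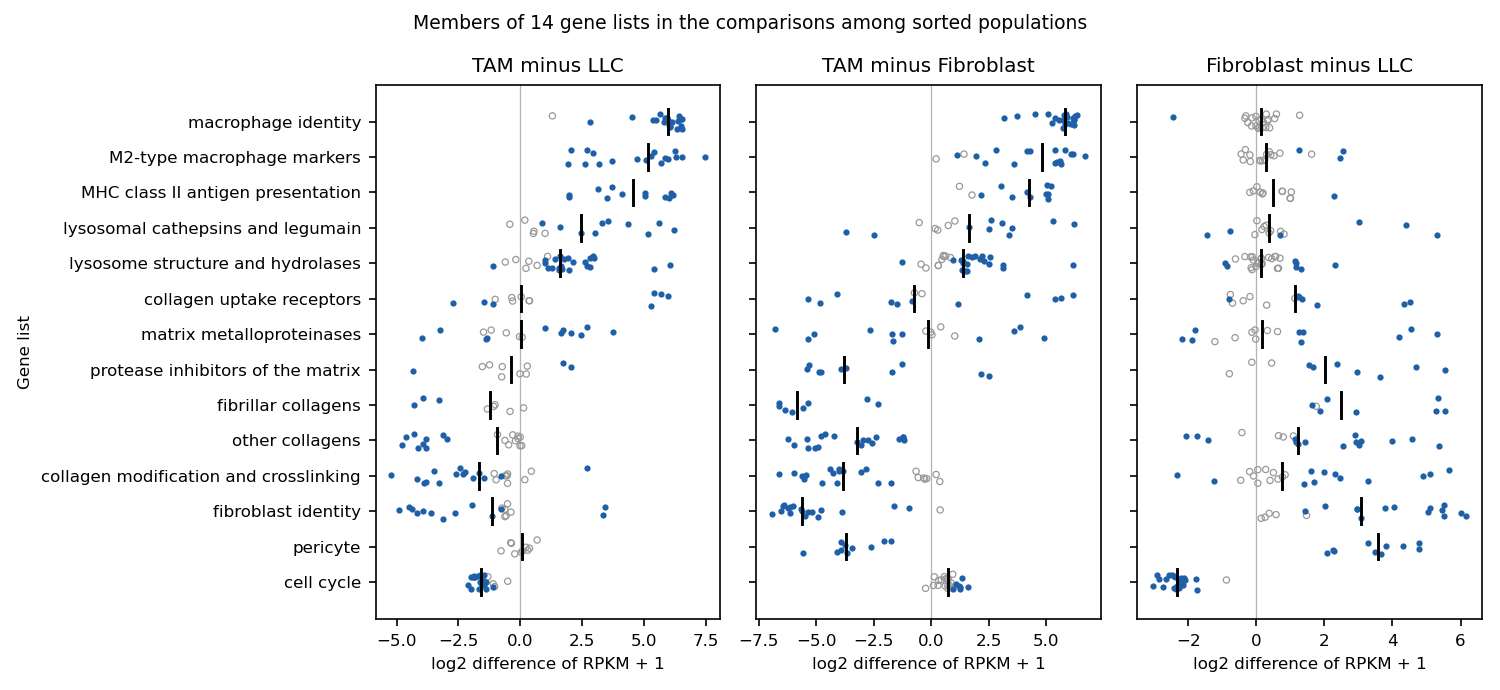
Log2 difference of each tested member of 14 gene lists in the 3 comparisons of sorted populations; each point is 1 gene, filled where its adjusted p was under 0.05, and each line is the list's median. All 8 fibrillar collagens lie below 0 in TAM minus Fibroblast, while matrix metalloproteinases spread to both sides, and in Fibroblast minus LLC their 6 higher and 3 lower members become 4 and 4 after quantile normalization.

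TAM were next set against the LLC cells, the other possible users of collagen in the tumor. Mrc1 stood at 514 ± 195 RPKM in TAM and 11.4 ± 13.6 in LLC (log2 5.98, SE 0.87, adjusted p = 0.00124). Retnla (NM_020509), a secreted protein of alternatively activated macrophages, reached 1707 ± 923 RPKM against 11.3 ± 11.8 (log2 7.46, SE 1.06, adjusted p = 0.00112), and the platelet-type chemokines Pf4 and Ppbp showed log2 differences of 7.07 and 6.83 (adjusted p = 0.000242 and 0.000113). Emr1, which encodes F4/80, and Ccr2, the chemokine receptor of inflammatory monocytes, stood at 196 ± 48.1 and 147 ± 61.1 RPKM in TAM (log2 5.66 and 5.34, adjusted p = 0.000822 and 0.00093). TAM were sorted on F4/80, so the Emr1 difference was in part set by the gate. On the LLC side, the Wnt regulators Dkk2 (NM_020265) and Apcdd1 (NM_133237) stood at 183 ± 27.2 and 192 ± 11.7 RPKM, with log2 differences of -5.31 and -5.32 in TAM (adjusted p = 9.87e-05 and 0.000114). The growth-linked noncoding RNA H19 was lower as well (log2 -5.11, adjusted p = 0.000513), and Mir675, which lies within it, was listed at 0 in both TAM libraries against 88.2 ± 57.6 RPKM in LLC.

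Lysosomal proteases were mostly higher in TAM than in LLC, while collagen uptake receptors lay in both directions. The lysosomal cathepsins and legumain had 10 higher and 0 lower members of 15, led by Ctss (log2 6.21, adjusted p = 0.000681) and Ctsc (log2 5.61), with a median of 2.86 (adjusted p = 1.02e-06, and adjusted p = 0.283 with an estimated correlation). Lgmn and Ctsb had log2 differences of 4.35 and 3.01 (adjusted p = 0.000265 and 0.00063). Ctsk was higher by a log2 of 1.59 (adjusted p = 0.00894). Without LLC replicate 1 its log2 was 1.03, and without TAM replicate 1 its call ended (adjusted p = 0.0543, range over its alternatives 0.0032 to 0.0543). Ctsl, at 834 ± 157 RPKM in TAM and 1107 ± 24.6 in LLC, did not pass (log2 -0.42, adjusted p = 0.453), and was lower only after quantile normalization (adjusted p = 0.0103, range 0.0103 to 0.791). Of 29 lysosome structure and hydrolase genes 22 were higher and 1 lower (24 and 1 adjusted over the list alone), such as Cd68 and Gm2a (log2 6.05 and 5.42), with a median of 2.00 (adjusted p = 9.5e-11, and adjusted p = 0.283 with an estimated correlation). The collagen uptake receptors gave 4 higher members, led by Mrc1 and Msr1 (log2 5.71), 3 lower ones, among them Mfge8 (log2 -2.72) and Itga10 (log2 -1.49), and 6 that did not pass (median 0.42, adjusted p = 0.15, and adjusted p = 0.659 with an estimated correlation). Mrc2 stood at 1.25 ± 1.18 RPKM in TAM and 3.23 ± 0.0672 in LLC (log2 -1.01, adjusted p = 0.0852), and passed without TAM replicate 2 (log2 -1.57, adjusted p = 0.0286, range 0.0286 to 0.434).

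Of 16 matrix metalloproteinases, 7 were higher in TAM than in LLC, led by Mmp8 (log2 3.74) and Mmp12 (log2 2.71), and 4 lower, led by Mmp3 (log2 -3.96) and Mmp11 (log2 -3.26), or 7 and 5 adjusted over the list alone (median 0.40, adjusted p = 0.21, and adjusted p = 0.545 with an estimated correlation). Mmp9 and Mmp13 were among the higher ones (log2 2.07 and 1.72, adjusted p = 0.00155 and 0.00517). Mmp14 stood at 119 ± 6.17 RPKM in TAM and 302 ± 33.8 in LLC (log2 -1.33, adjusted p = 0.0131). That call ended without LLC replicate 1 (adjusted p = 0.0576), LLC replicate 2 (0.0877), TAM replicate 1 (0.0614) or TAM replicate 2 (0.0757), in a range over its alternatives from 0.000479 to 0.0877.

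Several collagens were higher in LLC than in TAM. Of 8 fibrillar collagens 3 were lower in TAM, 0 higher and 5 did not pass (median -0.82, adjusted p = 0.133, and adjusted p = 0.659 with an estimated correlation). Col3a1 stood at 2824 ± 448 RPKM in LLC and 183 ± 162 in TAM (log2 -4.29, SE 0.75, adjusted p = 0.0029), and Col5a1 had a log2 of -3.94 (adjusted p = 0.000401). Of 19 other collagens 9 were lower in TAM, led by Col18a1 (log2 -4.78) and Col16a1 (log2 -4.64), and 10 did not pass (median -0.54, adjusted p = 0.00668, and adjusted p = 0.534 with an estimated correlation). Col1a1 and Col1a2 did not pass, at 70.5 ± 74.2 and 62.6 ± 66.0 RPKM in TAM and 134 ± 81.6 and 108 ± 84.3 in LLC (log2 -1.33 and -1.08, adjusted p = 0.234 and 0.367), nor did Mmp2 (log2 -1.49, adjusted p = 0.196). Without TAM replicate 1 these log2 differences turned to 0.02, 0.27 and 0.06, and without TAM replicate 2 Col1a1 and Mmp2 passed at -2.68 and -3.03 (adjusted p = 0.0213 and 0.00356). Over their alternatives the adjusted p ran from 0.0213 to 0.989 for Col1a1, from 0.0567 to 0.921 for Col1a2 and from 0.00356 to 0.935 for Mmp2. Beside these groups, TAM 2 held more of the fibroblast identity genes than TAM 1 did, at 2.75% and 0.512% of the Fibroblast level.

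**Figure D3:**
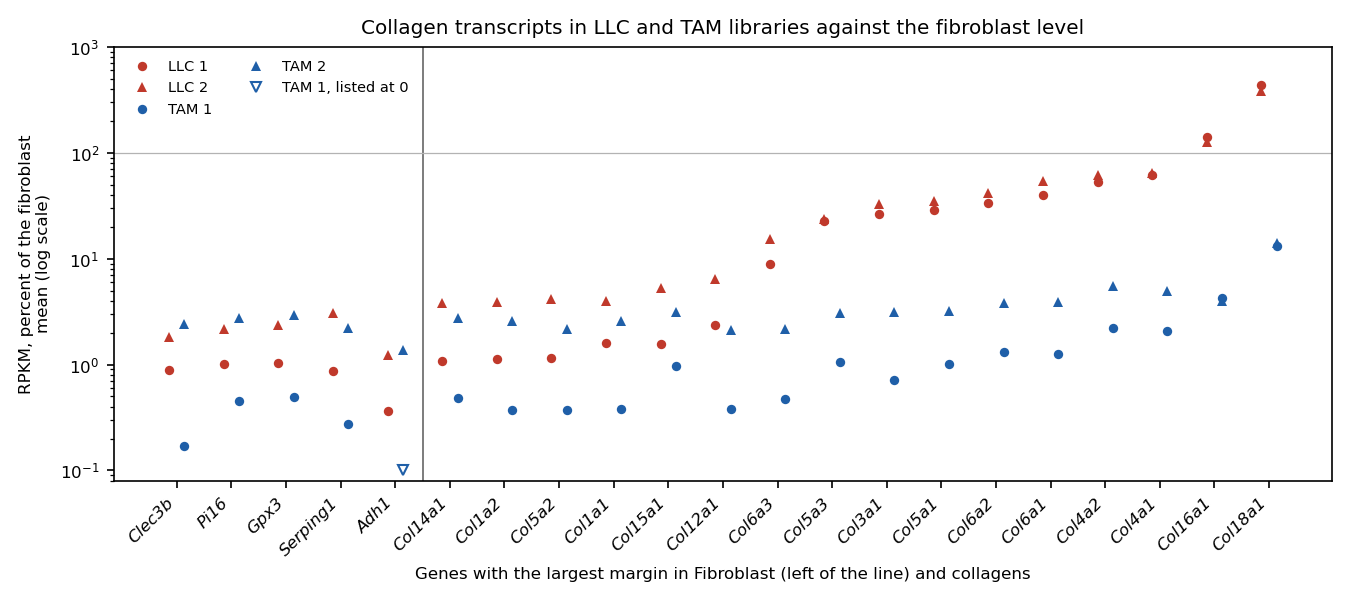
Level of the 5 genes with the largest margin in Fibroblast and of 16 collagens in the LLC and TAM libraries, as a percentage of the Fibroblast mean on a log axis; each point is 1 library and the open triangle marks Adh1, listed at 0 in TAM 1. These 5 genes reach at most 3.08% in an LLC library, while 9 collagens stand at 22.7% or more in both.

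Immune and matrix lists also set TAM and LLC apart. Macrophage identity genes were higher in 21 of 22, with a median of 6.37 (adjusted p = 1.28e-14, and adjusted p = 0.288 with an estimated correlation). All 18 M2-type macrophage markers were higher (median 5.55, adjusted p = 1e-13, and adjusted p = 0.283 with an estimated correlation), among them Arg1 at 1445 ± 304 against 20.2 ± 20.7 RPKM (log2 6.54). Of 13 M1-type markers 8 were higher, such as Irf5 (log2 5.03) and Il1b (log2 4.33), and 5 did not pass (median 3.54, adjusted p = 5.43e-06, and adjusted p = 0.283 with an estimated correlation). Monocyte origin genes were higher in 10 of 12, led by F13a1 and Ly6c2 (log2 6.12 and 5.42, median 3.46, adjusted p = 1.88e-06, and adjusted p = 0.283 with an estimated correlation). Beside these lists, genes of stress during tissue dissociation were higher in 9 of 20 and lower in 0, or 11 and 0 adjusted over the list alone (median 2.17, adjusted p = 3.06e-05, and adjusted p = 0.534 with an estimated correlation). Lists of other cell types were called higher in TAM as well. Neutrophil genes were higher in 5 of 8 and B and plasma cell genes in 2 of 9 (medians 3.55 and 2.10, adjusted p = 0.000479 and 0.00265, and adjusted p = 0.469 and 0.534 with an estimated correlation). T and NK cell genes were higher in 2 of 11 (1 adjusted over the list alone) and endothelial genes in 1 of 12 (medians 1.17 and 1.09, adjusted p = 0.0124 and 0.0418, and adjusted p = 0.556 and 0.611 with an estimated correlation). The endothelial call ended without LLC replicate 1 (adjusted p = 0.113) or TAM replicate 2 (0.358) and after the length correction (0.0676), in a range over its alternatives from 0.0022 to 0.611. The T and NK cell call ended after the length correction (adjusted p = 0.116, range 0.0031 to 0.556). Cell cycle genes were lower in TAM in 20 of 24 (22 adjusted over the list alone), such as Top2a (log2 -2.11) and Cdc20 (log2 -1.99), with a median of -1.19 (adjusted p = 2.23e-05, and adjusted p = 0.534 with an estimated correlation). Collagen modification and crosslinking genes were lower in 14 of 23 and higher in 1, with Plod2, which hydroxylates collagen lysines, at a log2 of -5.22 and Tgm2 at 2.69 (median -1.27, adjusted p = 0.00145, and adjusted p = 0.534 with an estimated correlation).

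By limma, 2048 genes were higher in TAM than in LLC and 3659 lower (1869 and 3088 with at least a 2-fold difference). The lower genes numbered 1956 without LLC replicate 1, 2323 without LLC replicate 2, 2207 without TAM replicate 1 and 2439 without TAM replicate 2. The share of called genes that were higher was 35.9%, against 46.3% after quantile normalization and 53% after the correction for transcript length. Camera called 15 lists higher and 5 lower, 0 of them with an estimated correlation, and fry called 18.

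Fibroblasts were set against LLC cells to ask which of these made the matrix and its fibroblast-type proteases. Clec3b (NM_011606), which encodes the plasminogen-binding protein tetranectin, and the secreted peroxidase Gpx3 stood at 965 ± 38.5 and 1973 ± 9.81 RPKM in Fibroblast, with log2 differences of 6.17 and 5.94 (adjusted p = 0.00207 and 0.000992). Complement C3 reached 2753 ± 842 RPKM against 51.2 ± 40.3 in LLC (log2 5.94, SE 0.83, adjusted p = 0.00156). Hmga2, a chromatin protein of embryonic and tumor cells, stood at 89.4 ± 2.13 RPKM in LLC and 1.61 ± 0.223 in Fibroblast (log2 -5.12, SE 0.23, adjusted p = 0.000272), and Nxf3, of the mRNA export factor family, at 45.2 ± 1.93 against 0.068 RPKM (log2 -5.43, adjusted p = 0.000272). Mrc2, Ctsk and Mmp2 were higher in Fibroblast by log2 differences of 4.34, 5.31 and 5.30 (adjusted p = 0.000419, 0.000272 and 0.00279), and Col1a1 and Col1a2 by 5.28 and 5.55 (adjusted p = 0.00258 and 0.0029). Fibroblast was sorted on GFP expressed with Col1a1, so the Col1a1 difference was in part set by the gate. Mmp13 was lower in Fibroblast (log2 -1.90, adjusted p = 0.00453). Col3a1, at 9519 ± 139 against 2824 ± 448 RPKM, did not pass (log2 1.76, adjusted p = 0.0991). The error of that test was pooled over all 4 groups. Col3a1 stood at 26.3 and 33.0% of its Fibroblast level in LLC 1 and LLC 2, but at 0.713 and 3.12% in TAM 1 and TAM 2. The missing call therefore does not show that Fibroblast and LLC were alike in Col3a1.

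Matrix lists lay on the Fibroblast side. Fibrillar collagens were higher in 7 of 8 (8 adjusted over the list alone) with a median of 2.95 (adjusted p = 2.05e-06, and adjusted p = 0.328 with an estimated correlation). Of 19 other collagens 12 were higher, such as Col14a1 (log2 5.36), and 3 lower, led by Col18a1 at 74.0 ± 22.1 RPKM in Fibroblast and 303 ± 26.6 in LLC (log2 -2.05), with a median of 1.68 (adjusted p = 6.78e-06, and adjusted p = 0.328 with an estimated correlation). Beside these groups, the fibrillar collagens of LLC 1 and LLC 2 stood at medians of 12.1% and 13.9% of the Fibroblast level and the fibroblast identity genes at 6.58% and 6.8%. None of the 6 fibrillar collagens behind these medians lay near them. Col1a1, Col1a2 and Col5a2 stood at 1.13 to 1.6% in LLC 1 and 3.92 to 4.16% in LLC 2. Col3a1, Col5a1 and Col5a3 stood at 22.7 to 29.1% in LLC 1 and 23.6 to 35.2% in LLC 2. Of 32 matrix glycoproteins and proteoglycans 19 were higher, led by Postn (log2 5.80), and 4 lower, led by the phosphoprotein Spp1 at 89.1 ± 52.2 against 1263 ± 223 RPKM (log2 -3.93), or 20 and 5 adjusted over the list alone, with a median of 2.70 (adjusted p = 9.33e-09, and adjusted p = 0.328 with an estimated correlation). Fibroblast identity genes were higher in 14 of 19 (15 adjusted over the list alone, median 3.53, adjusted p = 1.92e-10, and adjusted p = 0.328 with an estimated correlation). All 10 pericyte genes were higher, such as Rgs5 (log2 4.79), with a median of 4.04 (adjusted p = 1.76e-09, and adjusted p = 0.328 with an estimated correlation). Endothelial genes, of another cell type, were higher in 7 of 12 and lower in 0 (median 1.97, adjusted p = 5.24e-05, and adjusted p = 0.328 with an estimated correlation). Some immune lists were called higher too. Monocyte origin genes were higher in 4 of 12 and M2-type markers in 3 of 18. M1-type markers were higher in 4 of 13 and MHC class II genes in 1 of 12. Camera gave adjusted p = 0.000817, 0.00949, 0.0138 and 0.0324, or 0.328, 0.433, 0.368 and 0.492 with an estimated correlation. The M1-type and MHC class II calls of camera ended after quantile normalization (adjusted p = 0.0537 and 0.182). The MHC class II call also ended after the length correction (0.115) and without Fibroblast replicate 2. Without LLC replicate 1 the M2-type, M1-type and MHC class II calls all ended. LLC 1 and LLC 2 stood apart on macrophage identity genes, at medians of 0.502 and 3.02% of the TAM level. Fibroblast 1 and 2 stood at 1.22 and 1.81% (21 genes). Macrophage identity was not called (adjusted p = 0.154).

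Cell cycle genes were lower in Fibroblast than in LLC in 23 of 24 (24 adjusted over the list alone), such as Top2a at 9.52 ± 3 against 83.9 ± 15.2 RPKM (log2 -3.03) and Mcm5 (log2 -2.90), with a median of -1.88 (adjusted p = 1.33e-08, and adjusted p = 0.328 with an estimated correlation). Of 13 collagen uptake receptors 6 were higher, led by Itga11 (log2 4.53) and Mrc2, and 1 lower, or 7 and 1 adjusted over the list alone (median 1.60, adjusted p = 0.00651, and adjusted p = 0.368 with an estimated correlation). That call ended without LLC replicate 1 (adjusted p = 0.108, range over its alternatives 0.000246 to 0.368). Matrix metalloproteinases had 6 higher members, led by Mmp2 and Mmp23 (log2 4.53), and 3 lower ones, or 6 and 4 adjusted over the list alone, and 4 and 4 after quantile normalization (median 0.62, adjusted p = 0.0525, and adjusted p = 0.328 with an estimated correlation).

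Limma called 1726 genes higher in Fibroblast than in LLC and 3416 lower (1615 and 2769 with at least a 2-fold difference). The lower genes numbered 1132 without LLC replicate 1, 1754 without LLC replicate 2, 1344 without Fibroblast replicate 1 and 1135 without Fibroblast replicate 2. The number was 1480 after upper-quartile rescaling, 1835 after the correction for transcript length and 5230 with only the groups compared. The length correction gave 2707 higher genes, and the share of called genes that were higher moved from 33.6% to 59.6% with it, to 60% with upper-quartile rescaling and to 47.5% with quantile normalization. Of 32 lists camera called 22 higher and 2 lower, 0 of them with an estimated correlation, and fry called 12.

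Genes highest in 1 sorted population were counted to find what marks each. In TAM 1514 genes were called higher than in both other populations, led by Pf4, Ppbp, Arg1, Ccl6 and C1qc. Ccl6, a chemokine of myeloid cells, stood at 3169 ± 123 RPKM in TAM, 40.3 ± 40.8 in LLC and 37.8 ± 9.59 in Fibroblast. Fibroblast had 1198 such genes, led by Clec3b, Pi16, Gpx3, Serping1 and Adh1, or 781 with a filter at an RPKM of 5. LLC had 2099, led by Nxf3, Nptx1, Dkk2, Stc1 and F2r. Independent lists of these lengths would share 356, 298.2 and 939 genes. Simulations that kept the numbers of calls gave 899.1, 790.5 and 1767.8, because the comparisons share libraries. The LLC number was 1011 after upper-quartile rescaling, 1341 after quantile normalization and 1123 after the length correction. It was 3244 and 3238 without Total tumor replicates 1 and 2, 693 and 1054 without LLC replicates 1 and 2, 948 and 842 without Fibroblast replicates 1 and 2, and 1281 and 1300 without TAM replicates 1 and 2.

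TAM were then set against the whole tumor to see what the sorting enriched. Retnla stood at 1707 ± 923 RPKM in TAM and 51.8 ± 58.6 in Total tumor (log2 5.59, SE 1.06, adjusted p = 0.00655), and Lyz1, a lysozyme, at 161 ± 83.2 against 6.79 ± 2.95 (log2 4.33, SE 0.43, adjusted p = 0.000804). Dkk2, Tm4sf1 and Mxra8 were lower by log2 differences of -4.63, -4.57 and -4.48 (adjusted p = 0.000354, 0.000354 and 0.000371). Macrophage identity genes were higher in 18 of 22 (22 adjusted over the list alone), with a median of 3.05 (adjusted p = 8.53e-11, and adjusted p = 0.492 with an estimated correlation). The Total tumor libraries stood apart on this list, at medians of 9.56 and 23.2% of the TAM level in Total tumor 1 and 2 (21 genes). The lysosomal cathepsins and legumain were higher in 9 of 15 and the lysosome structure genes in 21 of 29 (10 and 24 adjusted over the list alone), with medians of 2.00 and 1.76 (adjusted p = 5.98e-06 and 7.75e-12, and adjusted p = 0.454 for each with an estimated correlation). Ctsb, Ctss, Lgmn and Mrc1 had log2 differences of 2.29, 2.93, 2.64 and 3.47 (adjusted p = 0.00397, 0.0247, 0.00399 and 0.0185). With only the groups compared, Ctsb, Ctss and Lgmn no longer passed (adjusted p = 0.113, 0.0786 and 0.0851). Over the alternatives the adjusted p ran from 0.00117 to 0.113 for Ctsb, 0.005 to 0.106 for Ctss, 0.000658 to 0.0851 for Lgmn and 0.00413 to 0.106 for Mrc1. The Mrc1 call ended without Total tumor replicate 2 (0.0631), TAM replicate 1 (0.0618) or TAM replicate 2 (0.106), and the Ctss call without Total tumor replicate 1 (0.077), Fibroblast replicates 1 and 2 (0.0571 and 0.0566) or TAM replicates 1 and 2 (0.106 and 0.0952) and after quantile normalization (0.0887). Ccr2 stood at 147 ± 61.1 RPKM in TAM and 33.2 ± 4.43 in Total tumor and did not pass (log2 2.06, adjusted p = 0.0615). Cell cycle genes were lower in 23 of 24 (24 adjusted over the list alone), such as Cdc20 (log2 -2.84, median -1.45, adjusted p = 1.32e-07, and adjusted p = 0.51 with an estimated correlation). Among 8 neutrophil genes 4 were lower, led by the calprotectin gene S100a9 at 16.1 ± 2.54 against 196 ± 174 RPKM (log2 -3.18, adjusted p = 0.0087, but 0.0566 without TAM replicate 2 and 0.0562 with only the groups compared, range 0.0016 to 0.0566), and Mmp8 (log2 1.79, adjusted p = 0.00497, but 0.135 with a pseudocount of 0.1, range 0.00132 to 0.135) was higher, or 4 and 3 adjusted over the list alone (median -1, adjusted p = 0.99, and adjusted p = 0.996 with an estimated correlation).

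In this comparison 1509 genes were higher in TAM and 3181 lower by limma. The higher genes numbered 777 without TAM replicate 1, 773 without TAM replicate 2, 629 with only the groups compared and 2680 after the length correction. The lower genes numbered 1612 and 1747 without TAM replicates 1 and 2, 2055 after quantile normalization and 1276 with only the groups compared. The share of called genes that were higher moved from 32.2% to 46.1% with upper-quartile rescaling, 50.4% with quantile normalization and 54% with the length correction. Camera called 11 lists higher and 7 lower, 0 of them with an estimated correlation, and fry called 14.

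LLC cells were set against the whole tumor to see what the tumor holds besides them. Genes of myeloid cells were lower in LLC. S100a8 stood at 0.496 ± 0.701 RPKM in LLC and 142 ± 143 in Total tumor (log2 -6.17, SE 0.76, adjusted p = 0.0217), S100a9 at 1.41 ± 1.2 against 196 ± 174 (log2 -6.09, SE 0.65, adjusted p = 0.019), and the monocyte gene Ly6c2 at 3.41 ± 3.45 against 75.2 ± 24.5 (log2 -4.34, SE 0.58, adjusted p = 0.0224). These 3 calls ended without LLC replicate 1 (adjusted p = 0.104 for each), Fibroblast replicate 1 (0.092), Fibroblast replicate 2 (0.0913), TAM replicate 1 (0.0571 to 0.0685) or TAM replicate 2 (0.0585 to 0.0682), and Ly6c2 without Total tumor replicate 2 (0.0611). They also ended without a filter on low values and with only the groups compared. Over the alternatives the adjusted p ran from 0.00795 to 0.269 for S100a8 and S100a9 and from 0.0116 to 0.269 for Ly6c2. Of 22 macrophage identity genes 4 were lower, or 21 adjusted over the list alone, with a median of -3.37 (adjusted p = 5.82e-18, and adjusted p = 0.261 with an estimated correlation). Beside them, these genes stood at medians of 0.502% and 3.02% of their TAM level in LLC 1 and LLC 2, and 9.56% and 23.2% in Total tumor 1 and 2 (21 genes). Of 8 neutrophil genes 6 were lower, or 8 adjusted over the list alone (median -2.68, adjusted p = 9.38e-12, and adjusted p = 0.261 with an estimated correlation). Endothelial genes were lower in 3 of 12 and T and NK cell genes in 2 of 11, or 8 and 7 adjusted over the list alone (medians -2.00 and -1.91, adjusted p = 2.01e-08 for each, and adjusted p = 0.261 for each with an estimated correlation). The Total tumor libraries themselves stood apart on these lists. The median log2 of library 2 over library 1 was -1.38 for T and NK cell, 1.57 for neutrophil, 1.44 for macrophage identity and 0.33 for endothelial genes. After a trend on transcript length was removed from this ratio, these medians were -2.06, 0.54, 0.73 and 0.14. None of 8 fibrillar and 19 other collagens passed (0 and 0 adjusted over the list alone by limma), with medians of -0.10 and 0.27 (adjusted p = 0.716 and 0.112, and adjusted p = 0.917 and 0.726 with an estimated correlation). The fibrillar median turned to 0.09 after quantile normalization, and camera ranked that list higher.

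Limma called 306 genes lower and 7 higher in LLC than in Total tumor, with 1423 genes at an unadjusted p under 0.05. The 7 higher ones, of which all but Mir23a were chosen after their values were seen, were 2310010J17Rik, Mir1949, Mir23a, Mir3473c, Mir6369, Mir6956 and Snord58b. With only the groups compared, limma called 0 genes, with 1026 at an unadjusted p under 0.05. The lower genes numbered 1492 without Total tumor replicate 1, 66 without Total tumor replicate 2, 0 without LLC replicate 1, Fibroblast replicate 1, Fibroblast replicate 2 or TAM replicate 1, and 10 without TAM replicate 2. The higher ones numbered 928 without Total tumor replicate 1, 3 without Total tumor replicate 2, 1 without TAM replicate 2 and 0 without LLC replicate 1, either Fibroblast replicate or TAM replicate 1. Camera called 16 lists lower and 0 higher, 0 with an estimated correlation, and fry called 5.

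Fibroblasts were set against the whole tumor as the remaining pair. C3 stood at 2753 ± 842 RPKM in Fibroblast and 54.5 ± 48.3 in Total tumor (log2 5.94, SE 0.83, adjusted p = 0.00174), Igfbp5, a binding protein of insulin-like growth factors, at 333 ± 14.4 against 6.95 ± 7.01 (log2 5.75, SE 0.87, adjusted p = 0.00238), and the Wnt antagonist Sfrp4 at 405 ± 15.8 against 7.86 ± 5.65 (log2 5.68, SE 0.73, adjusted p = 0.00127). S100a9 and Hmga2 were lower by log2 differences of -5.85 and -4.95 (adjusted p = 0.000847 and 0.000516). All 8 fibrillar collagens were higher, as were 15 of 19 other collagens, with medians of 3.16 and 2.14 (adjusted p = 2.34e-07 and 7.91e-08, and adjusted p = 0.312 for each with an estimated correlation). The limma call of Col3a1 ended without a filter on low values (log2 2.79, adjusted p = 0.0675). It also ended after quantile normalization (log2 1.79, adjusted p = 0.0914) and with only the groups compared (log2 2.79, adjusted p = 0.0902). Col18a1, which encodes a basement membrane collagen, was lower (log2 -1.56). Fibroblast identity genes were higher in 17 of 19 (median 4.12, adjusted p = 1.1e-12, and adjusted p = 0.312 with an estimated correlation), and pericyte genes in 10 of 10 (median 3.19, adjusted p = 1.19e-08, and adjusted p = 0.312 with an estimated correlation). All 24 cell cycle genes were lower (median -2.29, adjusted p = 3.29e-09, and adjusted p = 0.361 with an estimated correlation), and so were 20 of 22 macrophage identity genes (21 adjusted over the list alone, median -2.66, adjusted p = 0.000127, and adjusted p = 0.644 with an estimated correlation). Total tumor 1 and 2 differed on the macrophage list, at medians of 9.56 and 23.2% of the TAM level.

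Here limma called 1613 genes higher and 3988 lower in Fibroblast. The lower genes numbered 1611 and 1264 without Fibroblast replicates 1 and 2, 1760 after upper-quartile rescaling, 2428 after quantile normalization, 2002 after the length correction and 2003 with only the groups compared, and the higher ones 2619 after the length correction. The share of called genes that were higher moved from 28.8% to 56% with upper-quartile rescaling, 47.9% with quantile normalization, 56.7% with the length correction, and 41.8% and 46.6% without Fibroblast replicates 1 and 2. Camera called 12 lists higher and 5 lower, 0 of them with an estimated correlation, and fry called 14.

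Genes higher in Total tumor than in each sorted population were sought as signs of cells outside all 3 sorts. There were 21, led by S100a9, S100a8, Mcpt4, Gzmb and Hdc. Mcpt4 and Hdc, genes of mast cells, stood at 15.1 ± 5.12 and 11.6 RPKM in Total tumor, and Gzmb, a protease of cytotoxic lymphocytes, at 10.7 ± 7.24. Independent lists would share 21.9 genes and simulations with the same numbers of calls 182.2. The number was 482 without Total tumor replicate 1, 11 without Total tumor replicate 2, 7 without LLC replicate 2, 2 without TAM replicate 2 and 0 without LLC replicate 1, either Fibroblast replicate or TAM replicate 1. With only the groups compared it was 0, because limma then called no gene between LLC and Total tumor.

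**Figure D4:**
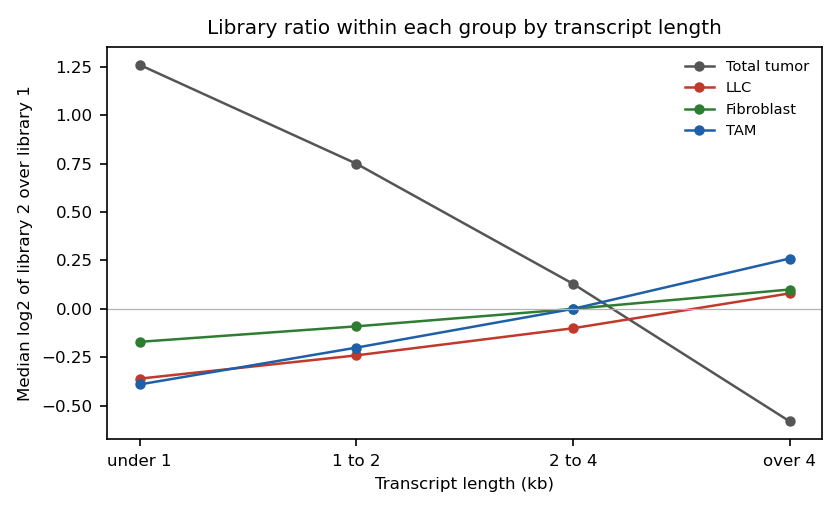
Median log2 ratio of library 2 to library 1 in 4 bins of transcript length for each group; each point is the median over the genes of a bin. In Total tumor the median falls from 1.26 under 1 kb to -0.58 over 4 kb, and in LLC, Fibroblast and TAM it stays between -0.39 and 0.26.

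The libraries of each group also differed by transcript length, as the plot of ratios by length shows. Across genes, which are not independent replicates, Spearman's rho of the log2 ratio with length was -0.66 in Total tumor, 0.39 in LLC, 0.28 in Fibroblast and 0.46 in TAM.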

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

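The correction for transcript length and the fit of protein-coding accessions were chosen after the data were seen. Of 549 called gene results, 348 stayed past the threshold in every alternative that gave a value and 0 reversed. Of the uncalled differences between TAM and LLC, Mmp2, Col1a1 and Col1a2 reversed without TAM replicate 1, to 0.06, 0.02 and 0.27, and lay at -3.03, -2.68 and -2.43 without TAM replicate 2. Genes higher in LLC than in Total tumor numbered 4 with a pseudocount of 5, 2 without a filter, 2 with a filter at RPKM 5, 3 after the length correction and 0 with protein-coding accessions. The lower ones numbered 176 with a pseudocount of 5, 10 without a filter and 197 after upper-quartile rescaling. With only the groups compared, limma called 0 higher and 0 lower, with 1026 at an unadjusted p under 0.05. Genes highest in Total tumor then numbered 0, and 7 with a pseudocount of 0.1, 4 without a filter, 11 with a filter at RPKM 5, 8 after upper-quartile rescaling, 7 after quantile normalization, 10 after the length correction and 11 with a term for the replicate number. Genes highest in Fibroblast numbered 781 with a filter at RPKM 5, and genes highest in LLC 1011 after upper-quartile rescaling, 1341 after quantile normalization and 1123 after the length correction. Between Fibroblast and LLC, 1480 genes were lower after upper-quartile rescaling, 5230 with only the groups compared and 1835 after the length correction, which gave 2707 higher. Between TAM and Total tumor, 629 were higher and 1276 lower with only the groups compared, 2055 lower after quantile normalization and 2680 higher after the length correction. Between Fibroblast and Total tumor, 1760 were lower after upper-quartile rescaling, 2428 after quantile normalization, 2003 with only the groups compared and 2002 after the length correction, which gave 2619 higher. The cause of these moves was not tested. With an estimated correlation camera called 0 lists in all 6 comparisons, and fry called 12 between Fibroblast and LLC and 5 between LLC and Total tumor. Leaving out 1 library in turn assumes that the lone library of a group varies like the other groups. It gave 1956 to 4843 genes lower in TAM than in LLC, 1382 to 3328 higher in TAM than in Fibroblast, 1132 to 5104 lower in Fibroblast than in LLC, 773 to 1869 higher and 1612 to 4121 lower in TAM than in Total tumor, 0 to 928 higher and 0 to 1492 lower in LLC than in Total tumor, and 1264 to 5109 lower in Fibroblast than in Total tumor. Genes highest in LLC ran from 693 to 3244 and those highest in Total tumor from 0 to 482. Replicate numbers are shared between groups, but nothing in the labels says that they pair. Correlations between the groups' replicate deviations were positive between the sorted populations (0.21 for LLC and Fibroblast, 0.27 for LLC and TAM, 0.16 for Fibroblast and TAM) and negative for Total tumor (-0.23 with LLC, -0.18 with Fibroblast, -0.36 with TAM). Replicate 1 had the higher estimated depth in each group, so depth alone would not give the opposite sign in Total tumor. Spearman's rho of the library ratio with transcript length had the same signs, -0.66 in Total tumor and 0.39, 0.28 and 0.46 in LLC, Fibroblast and TAM. Effects of length and depth are therefore not separated from pairing. With a term for the replicate number 5044 of 5707 calls between TAM and LLC were shared. It was 4128 of 4614 between TAM and Fibroblast and 4362 of 5142 between Fibroblast and LLC. Against Total tumor it was 3950 of 4690 for TAM, 235 of 313 for LLC and 4793 of 5601 for Fibroblast. Depth left 1 read on a 2 kb transcript at up to 0.117 RPKM, so genes at that level carry little information.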

Other observations

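Of the explanations weighed in this part, all but transcript length for the neutrophil and the T and NK cell genes had their tests chosen after the result was seen, and the tests of gene lists were chosen earlier. TAM also carried genes of antigen presentation and antiviral response. All 12 genes of MHC class II antigen presentation were higher in TAM than in LLC, with Cd74, the invariant chain, at 4273 ± 1680 against 82.6 ± 87.7 RPKM (log2 6.20, median of the list 4.95, adjusted p = 1.16e-08, and adjusted p = 0.283 with an estimated correlation). Of 18 type I interferon genes 10 were higher, such as Mx1 (log2 3.37) and Irf7, and 1 lower (11 and 1 adjusted over the list alone), with a median of 1.67 (adjusted p = 7.71e-06, and adjusted p = 0.283 with an estimated correlation). Of 24 chemokine genes 16 were higher and 2 lower, or 18 and 2 adjusted over the list alone (median 3.26, adjusted p = 7.01e-07, and adjusted p = 0.283 with an estimated correlation).

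Fibroblast was also set against LLC for secreted factors. Cxcl12, which holds CXCR4-positive cells in tissue, stood at 518 ± 147 RPKM in Fibroblast and 13.2 in LLC (log2 5.46), and of 14 complement genes 7 were higher than in LLC and 0 lower, with a median of 2.45 (adjusted p = 7.29e-05, and adjusted p = 0.328 with an estimated correlation). Of 10 protease inhibitors 7 were higher than in LLC, such as Timp3 at 126 ± 32.7 against 1.76 RPKM (log2 5.55), with a median of 2.49 (adjusted p = 1.77e-05, and adjusted p = 0.278 with an estimated correlation). Of 19 hypoxia and glycolysis genes 10 were lower than in LLC, such as Egln3 (log2 -4.17), and 1 higher (10 and 2 adjusted over the list alone), with a median of -0.83 (adjusted p = 0.149, and adjusted p = 0.683 with an estimated correlation).

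Fibrillar collagen transcripts were present in both TAM libraries at different levels. Collagen transcripts of the TAM themselves, at the level measured in TAM 2, are argued against by the ratio of TAM 2 to TAM 1, whose lower quartile over 6 fibrillar collagens was 3.48 against an upper quartile of 1.05 over 21 macrophage identity genes. Fibroblast RNA carried into the TAM libraries may explain the difference, since the median ratio was 5.13 over the collagens and 4.24 over 17 fibroblast identity genes (quartiles 2.78 to 6.14). The genes with the largest margin in Fibroblast, Clec3b, Pi16, Gpx3, Serping1 and Adh1, stood at 0.171, 0.449, 0.489, 0.275 and 0% of their Fibroblast level in TAM 1 and at 2.41, 2.75, 2.96, 2.21 and 1.36% in TAM 2. Sorting GFP-negative cells would remove fibroblasts, and whether it leaves RNA they released was not tested.

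Of 16 collagens with at least 20 RPKM in Fibroblast, 9 stood at 10% of that level or more in both LLC libraries, the lowest at 22.7%, and Col6a3 in LLC 2 alone, at 8.88 and 15.3% in LLC 1 and LLC 2. RNA like that of the sorted Fibroblast, carried into the LLC libraries, is argued against as the whole source for these 10, since it would raise every fibroblast gene, and Clec3b, Pi16, Gpx3, Serping1 and Adh1, the genes with the largest margin in Fibroblast, reached at most 3.08% there. Those 5 were chosen for being low in LLC and TAM. The 17 fibroblast identity genes, from a list fixed earlier, were split, with quartiles of 1.18 to 27.3% in LLC 1 and 3.52 to 41.2% in LLC 2. RNA of fibroblasts unlike the sorted ones was not tested. Expression by the LLC cells may account for these 10 collagens, a hypothesis found and tested on the same data. The other 6, Col1a1 and Col1a2 among them, had medians of 1.37% in LLC 1 and 4.09% in LLC 2, above the highest of those 5 genes in the same library (1.04 and 3.08%). For them, transcripts of the LLC cells at the level of LLC 2 are argued against, since the lower quartile of the ratio of LLC 2 to LLC 1 was 2.87 against an upper quartile of 1.05 over all 3982 tested genes with at least 20 RPKM in LLC and 1.24 over the 9 collagens, while carried-over RNA stays open, with a median ratio of 3.39 at the edge of the quartiles over those 5 genes (2.15 to 3.39), and sorting dTomato-positive cells would remove fibroblasts.

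Total tumor 2 differed from Total tumor 1 by cell-type lists. Dependence on transcript length alone is argued against, since after its trend was removed the neutrophil list lay at percentile 98.8 and the T and NK cell list at percentile 0.0 of 10000 random lists matched on expression and length, and 14 of 31 lists lay outside the central 95% (2 above and 12 below). A lower share of LLC cells alone is argued against as well, since the macrophage median exceeded the T and NK cell median by 2.79 on the log2 scale. A lower share together with a change among the immune cells stays open, as genes of the LLC cells were not tested here. Hosts of different sex may be part of the difference, since 4 Y-linked genes summed to 8.82 RPKM in Total tumor 2 and to at most 0.101 in any other library, and Xist was lower in it than in Total tumor 1 (log2 -2.72, and -1.34 after the length trend was removed). Xist stood at 35.7 and 39.3 RPKM in LLC 1 and LLC 2 and at 7.79 in Total tumor 2. Host sex would leave the Xist of the LLC cells in place, so it does not by itself settle that fall. A wrongly labelled library stays open, and the labels name no difference between the 2 Total tumor libraries.

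Genes of stress during tissue dissociation were higher in 9 of 20 in Fibroblast than in LLC (median 2.35, adjusted p = 1.34e-05, and adjusted p = 0.368 with an estimated correlation). They were higher than in Total tumor in 9 of 20 in TAM and 4 of 20 in Fibroblast, or 9 and 3 adjusted over the list alone (medians 1.96 and 1.87, adjusted p = 6.02e-06 and 2.35e-05, and adjusted p = 0.525 and 0.604 with an estimated correlation), but Total tumor 2 and Total tumor 1 themselves differed on this list by a median log2 of -1.4. In Fibroblast 2 the epithelial keratins Krt8, Krt18 and Krt19, chosen after their values were seen, stood at 21.2, 44.9 and 99.6 RPKM, against 2.14, 5.59 and 16.5 in Fibroblast 1. Retnla stood at 93.2 and 10.4 RPKM in Total tumor 1 and 2 and at 1054 and 2360 in TAM 1 and 2. Mertk, a macrophage receptor for dying cells, stood at 34.7 and 41.2% of its TAM level in LLC 1 and 2.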
